A study of Mus musculus with 28 samples.

How the data were processed

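Polyadenylated RNA was profiled in 28 libraries from 3 mouse cell lines, each grown alone or in direct contact with a partner line. EO771 is a mouse breast cancer line, C2C12 is a mouse muscle line used here as differentiated myotubes, and MLg is a mouse lung fibroblast line. There were 7 groups of 4 libraries: each of the 3 lines alone, EO771 and C2C12 from their shared culture, and EO771 and MLg from theirs. RNA was extracted with an RNeasy kit and sequenced from TruSeq stranded mRNA libraries, per the labels' protocols. How the lines of a shared culture were separated before extraction, and whether replicates came from separate cultures, is not given in the sources used here. The p-values below therefore measure the spread between these libraries, which may be technical in part.

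The deposited values are raw counts per gene, 1 table per library, with no normalization in the deposited files. The submitters' processing notes name fastp, STAR 2.7.10a, featureCounts, Subread 2.0.1 and DESeq2 without saying which step each served; the genome build and annotation are not given in the sources used here. All 55536 Ensembl gene identifiers in the tables were found in the GENCODE M21 primary assembly annotation of GRCm38, which was used for symbols and coordinates (1-based); 55450 identifiers had a symbol of their own and 86 did not. Replicates are named as in the labels, with an R number and a running number, such as R3-1; the meaning of the R number is not stated. The file names of a pair of libraries of EO771 with C2C12 carry each other's name, and the assignment recorded with the series was followed. In 5 libraries every count was even (EO771 with C2C12 R5-1, R6-1 and R3-1, MLg with EO771 R5-1 and R6-1), whereas 41.6% to 44.8% of the nonzero counts were odd in the other 23. All 5 were co-cultured libraries, so a difference in how they were counted would go in part with the group. Halving these counts, tried below, changes their scale only. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom over the 42 replicate pairs, for genes with at least 20 counts, was 9.42.

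Total counts ran from 27.6 M to 96.5 M per library, and the lowest total was 14.5 M with the even counts halved. A count of 0 allows up to 3 counts, which is 0.109 CPM (counts per M total counts) in the library with the lowest total and 0.0311 CPM in the one with the highest. Such floors cover counting error only. CPM values were computed from the deposited counts and the library totals. Genes that overlap or have close copies can share reads, and the strand setting of the counting is not given in the sources used here.

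Differential expression was tested with edgeR 4.0.16 (R 4.3.3) and its quasi-likelihood F test, with TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over all genes tested; genes with an adjusted p under 0.05 are called changed. Every adjusted p below comes from this test unless a list test is named. The 12 EO771 libraries were fitted together with 1 mean per group, the C2C12 and MLg libraries each in a fit of their own, and all 16 host libraries in a further fit that gave the difference between the C2C12 and MLg responses and the contrast of the lines grown alone. Values are log2 fold changes with standard errors (SE), or mean CPM with standard deviations (SD, n = 4 per group).

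Gene lists were written before the data were examined: hypoxia response, glycolysis, oxidative phosphorylation, S phase and DNA replication, G2/M and mitosis, p53 targets and CDK inhibitors, cholesterol synthesis, amino acid stress (ATF4 targets), ER chaperones, interferon response, NF-kB and inflammatory cytokines, TGF-beta response and contractile genes, extracellular matrix, fibroblast markers, epithelial markers, sarcomere and myotube markers, myogenic regulators, muscle atrophy, macrophage and endothelial markers, and dissociation and heat shock. Each list was tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison. It was tested again with the correlation estimated from the data, and with fry. Called members were counted with adjustment over all genes and over the list alone.

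A rule fixed before the data were examined named the genes: per comparison, the 5 largest rises and 5 largest falls (3 each for the contrasts of host lines) at a mean of at least 5 CPM with every library of one group above the other's, the 3 largest partner-enriched rises, a panel of 13 growth and hypoxia genes in the comparisons of co-cultured groups, and up to 2 members of each list (4 for hypoxia and cell cycle lists). The text names a subset, chosen after the values were seen. Of the genes first picked, 16 were then left out because the call ended when some single library was left out, so the named genes are steadier than the rule's full set. Over that full set the number of calls ended in this way was 1 of 61 in EO771 with C2C12 against alone, 11 of 40 in EO771 with MLg against alone, 5 of 59 between the co-cultured EO771 groups, 10 of 22 in C2C12, 11 of 55 in MLg, 10 of 19 for the difference of host responses and 3 of 49 between the host lines alone.

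Because RNA of the partner line could be present in a library, carry-over was estimated as the median, over genes specific to the partner (at least 20 CPM in the partner alone and at most 0.2 CPM in the own line alone), of the library's CPM divided by the partner's mean CPM in co-culture. A gene is called partner-enriched where its mean CPM in the partner line alone was more than 4 times that in the own line alone. Genes that rise in the partner only in co-culture can be missed by this rule.

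Alternatives fixed beforehand were DESeq2 1.42.0, RLE normalization, no low-count filter, all 28 libraries in 1 fit, the R number as a block, leaving out each library, leaving out partner-enriched genes and subtracting the estimated partner counts. After the data were seen, 4 more were added: even counts halved, no C2C12 libraries numbered R3, no EO771 with MLg libraries R5-1 and R7-1 (mitochondrial shares of 11.7% and 10.0%), and C2C12 counts subtracted at the share of muscle transcripts, with MLg counts subtracted at their median share as before. Whether R numbers pair libraries was checked from the correlation of same-numbered libraries' deviations from their group means. Every correlation was above 0.1 only in C2C12 (0.284 to 0.566 over 4 pairs), so in C2C12 with EO771 against alone blocked values are given for the number of genes called and for the lists whose call the block ended or whose called median it moved by over 1.5 times. Elsewhere in the report they are given for cell cycle lists and Gbp7, whose calls they change, and for the hypoxia list in EO771 with C2C12. For the difference of host responses they are also given for the sarcomere list and the number of genes called. Among the C2C12 libraries, R2 occurs only alone and R6 only with EO771, so the blocked values in C2C12 rest on R3 and R5.

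The tests were checked on simulated counts with 100 genes changed at each size. For EO771 with C2C12 against alone, 91% of changes of 1 on the log2 scale and 99% of changes of 2 were recovered. For C2C12 the shares were 50% and 90%, for MLg 93% and 99%, and for the difference of host responses 55% and 87%. Of the genes called in these simulations, 5.65%, 3.16%, 5.58% and 4.40% in the same order were unchanged ones, and 1 list that had not been raised was called in MLg. Simulated genes were drawn independently of each other and without differences between R numbers. False calls that come from correlated genes or from such differences are therefore not covered by these shares. Simulated carry-over of 1% and 5% was estimated as 1.04% and 5.06%. It was added at 1 share for all transcripts, from the same mean that the estimate divides by. The check therefore covers the computation only, and not shares that differ between transcripts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.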

Results

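Gene expression was measured in cells taken from direct co-cultures, in which EO771 breast cancer cells were kept on a layer of C2C12 myotubes or of MLg lung fibroblasts, and in each line grown alone. The series title names hypoxia as a driver of an antiproliferative effect of muscle cells on the cancer cells, and the comparisons below give particular room to hypoxia and cell cycle genes. Each of the 7 groups held 4 libraries. Total counts per library ran from 34.1 to 39.0 M in EO771 alone, 27.6 to 47.4 M in EO771 with C2C12, 33.2 to 48.3 M in EO771 with MLg, 54.8 to 96.5 M in C2C12 alone, 36.5 to 63.0 M in C2C12 with EO771, 61.7 to 69.7 M in MLg alone and 33.8 to 57.5 M in MLg with EO771. Gene positions are given on GRCm38.

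RNA of the partner line was detectable in every co-cultured library. Transcripts specific to C2C12 (413 genes) were present in EO771 with C2C12 at 1.02% ± 0.365 (SD, n = 4) of their level in the co-cultured C2C12 libraries, against 0% in EO771 alone. Transcripts specific to MLg (370 genes) stood at 1.59% ± 0.397 (SD, n = 4) in EO771 with MLg, again against 0% in EO771 alone. In the other direction, EO771-specific transcripts reached 4.27% ± 0.898 (SD, n = 4) in C2C12 with EO771 (68 genes) and 8.56% ± 3.30 (SD, n = 4) in MLg with EO771 (84 genes), against 0.0199% and 0.0394% in those lines alone. These genes were chosen for near absence in the line alone, so the levels alone are low by construction. The partner's own level is therefore given beside several of the partner-enriched genes.

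**Figure D1:**
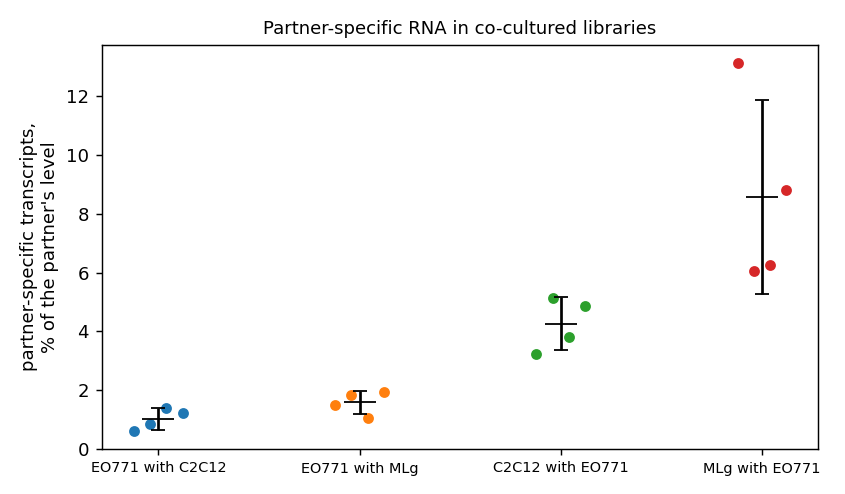
Partner-specific transcripts in each co-cultured library, as a percentage of their level in the partner line (vertical axis), for the 4 co-cultured groups; points are libraries, and the bar is the mean with its SD (n = 4). The means rise from 1.02% in EO771 with C2C12 to 8.56% in MLg with EO771.

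EO771 cells kept on myotubes had higher levels of hypoxia response and glycolysis genes and lower levels of DNA replication genes than EO771 cells alone. With an estimated correlation only the hypoxia list passed (camera, adjusted p = 0.0145), and the glycolysis and S phase lists did not (adjusted p = 0.111 and 0.305). Slc2a1, which encodes the glucose transporter GLUT1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), rose 2.84-fold, from 170 ± 17.7 to 507 ± 43.1 CPM (SD, n = 4, log2 1.51 ± 0.112 SE, adjusted p = 2.3e-08). The mitophagy receptor gene Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519) rose 9.24-fold, from 3.42 ± 0.574 to 33.3 ± 2.07 CPM (SD, n = 4, adjusted p = 3.59e-09). Egln3, which encodes a prolyl hydroxylase of HIF proteins (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), rose 8.66-fold to 160 ± 40.7 CPM (SD, n = 4, adjusted p = 6.87e-10). Mcm10, a replication initiation factor gene (ENSMUSG00000026669, chromosome 2, 4989714 to 5012791), fell from 156 ± 10.3 to 78.5 ± 17.1 CPM (SD, n = 4, log2 -1.06 ± 0.135 SE, adjusted p = 9.99e-06). The CDK inhibitor gene Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose 3.62-fold to 132 ± 30.5 CPM (SD, n = 4, adjusted p = 1.65e-08). In each of these 5 genes all 4 co-cultured libraries lay on one side of all 4 controls.

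Of the 29 measured hypoxia response genes, 24 were higher and 2 lower, with the same numbers adjusted over the list alone. Their median log2 fold change was 1.48 (camera, adjusted p = 2.45e-16; adjusted p = 0.0145 with an estimated correlation). The vasodilator peptide gene Adm rose 5.58-fold (adjusted p = 2.98e-06), Pdk1, which encodes a pyruvate dehydrogenase kinase, 2.30-fold (adjusted p = 2.98e-07), Ndrg1 2.79-fold (adjusted p = 2.24e-09) and the angiogenic factor gene Vegfa 1.45-fold (adjusted p = 0.00398). Among the 24, 10 were partner-enriched: C2C12 alone held 95.7 CPM of Bnip3, 72.7 CPM of Egln3, 460 CPM of Ndrg1, 188 CPM of Car9 and 1231 CPM of the collagen crosslinking enzyme gene Lox. Lox rose from 0.232 ± 0.168 to 10.2 ± 3.55 CPM and Car9, a carbonic anhydrase gene, from 1.48 ± 0.505 to 4.66 ± 1.98 CPM (SD, n = 4). The call of Car9 ended once partner counts were subtracted (adjusted p = 0.0853). With C2C12 counts subtracted at the share of muscle transcripts, the call of Vegfa ended (adjusted p = 0.0871). With partner-enriched genes left out, the hypoxia list kept a median of 1.24. Hif1a itself, whose protein is regulated mainly by degradation, measured 346 ± 11.9 CPM alone and 368 ± 35.9 CPM in co-culture (SD, n = 4, log2 0.01, adjusted p = 0.934). Of 16 glycolysis genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.74 (camera, adjusted p = 2.56e-08, adjusted p = 0.111 with an estimated correlation). Among them were Tpi1 (2.88-fold), Hk1 (2.86-fold) and the lactate dehydrogenase gene Ldha (1.80-fold). Of the 28 oxidative phosphorylation genes edgeR called 0 (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 by DESeq2), with a median of -0.06 (camera, adjusted p = 0.478).

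Of the 28 S phase and DNA replication genes, 20 were lower and 0 higher (23 and 0 adjusted over the list alone). Their median was -0.45 (camera, adjusted p = 4.44e-09; adjusted p = 0.305 with an estimated correlation). With C2C12 counts subtracted at the share of muscle transcripts, 8 were lower and 0 higher, and the median was -0.32 (camera, adjusted p = 0.000207). The origin licensing gene Cdc6 fell by 1.00 on the log2 scale (adjusted p = 4.85e-05). In the G2/M and mitosis list, 10 of 28 genes were lower and 1 higher (12 and 1 adjusted over the list alone). The median was -0.25 (camera, adjusted p = 0.000431, adjusted p = 0.595 with an estimated correlation, fry adjusted p = 0.0811). Without EO771 with C2C12 R3-1 the median was -0.14 (camera, adjusted p = 0.0147). With C2C12 counts subtracted at the share of muscle transcripts, the list was not called (median -0.095, camera adjusted p = 0.338; 1 lower and 2 higher). Foxm1, a transcription factor gene of mitotic genes, fell by 0.53 (adjusted p = 0.000907) and Ccnb1, which encodes cyclin B1, by 0.56 (adjusted p = 0.00565). The proliferation marker Mki67 was not called, at 126 ± 10.2 CPM alone and 147 ± 31.0 CPM in co-culture (SD, n = 4, adjusted p = 0.40). Myc fell by 0.44 on the log2 scale (adjusted p = 0.0149) while the cyclin D1 gene Ccnd1 rose by 0.49 (adjusted p = 0.0066). At the share of muscle transcripts the calls of Myc (adjusted p = 0.175) and Ccnb1 (0.0939) ended. In a fit of all 28 libraries those of Myc (adjusted p = 0.264), Ccnb1 (0.195), Foxm1 (0.0775) and Ccnd1 (0.0564) ended. The p53 targets and CDK inhibitors split, with 5 of 20 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.74).

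Among the other lists, 19 of 27 interferon response genes were higher and 0 lower (the same adjusted over the list alone). The median was 0.97 (camera, adjusted p = 9.32e-07, adjusted p = 0.314 with an estimated correlation). The RNA sensor gene Ddx58 rose 3.32-fold and the antiviral gene Oas1a 2.67-fold. When C2C12 counts were subtracted at the share of muscle transcripts, the median of this list was 0.03 and its call ended (camera, adjusted p = 0.976). Cholesterol synthesis genes were higher in 12 of 23 cases and never lower (the same adjusted over the list alone; median 0.31, adjusted p = 0.00568, adjusted p = 0.595 with an estimated correlation). Mvd rose 2.08-fold. ER chaperones were lower in 9 of 17 cases and higher in 3 (11 and 3 adjusted over the list alone; median -0.24, adjusted p = 0.0222, adjusted p = 0.509 with an estimated correlation). Hspa5, which encodes BiP, fell by 0.62 on the log2 scale. Of 17 amino acid stress genes, 5 were lower and 2 higher, also adjusted over the list alone. Phgdh, a serine synthesis enzyme gene, fell by 0.63, and the list's median of -0.14 and mean of 0.13 differ in sign (camera adjusted p = 0.194). The largest rises outside partner-enriched genes included the copper transporter gene Atp7b (ENSMUSG00000006567, chromosome 8, 21992785 to 22060305; from 0.37 to 17.8 CPM, adjusted p = 1.62e-09), Sncb (0.125 to 6.42 CPM) and Ly6g (0.52 to 7.60 CPM). The largest falls included the acute phase gene Saa3 (6.26 to 0.955 CPM, adjusted p = 6.58e-07), the complement gene C3 (47.3 to 8.04 CPM) and Id3, an inhibitor of helix-loop-helix factors (20.8 to 4.44 CPM).

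Muscle transcripts were present in EO771 with C2C12. All 22 measured sarcomere and myotube markers (median 4.70, camera adjusted p = 2.05e-19, adjusted p = 0.0675 with an estimated correlation) and 10 of 12 myogenic regulators (median 5.57, adjusted p = 9.13e-09, adjusted p = 0.0675 with an estimated correlation) were higher, with the same numbers adjusted over the list alone. Every one of these was partner-enriched. Myh1, a myosin heavy chain gene, was at 18.1 ± 10.4 CPM against 0 in all EO771 alone libraries (SD, n = 4), and at 236 CPM in C2C12 alone. Of the 25 extracellular matrix genes, 17 were higher and 1 lower (18 and 1 adjusted over the list alone; median 1.21, adjusted p = 4.60e-10, adjusted p = 0.229 with an estimated correlation). Of these 14 were partner-enriched, such as the fibronectin gene Fn1 at 206 ± 94.9 CPM (SD, n = 4) beside 27560 CPM in C2C12 alone. Of 15 fibroblast markers, 10 were higher and 1 lower (11 and 1 adjusted over the list alone; median 1.87, adjusted p = 2.04e-07, adjusted p = 0.111 with an estimated correlation), 9 of them partner-enriched. With the partner counts subtracted, the matrix list was no longer called (median 0.57, camera adjusted p = 0.391) and the fibroblast list's median was -0.38. That subtraction put Fn1 at -8.58, below its control, so it removed more of Fn1 than carry-over brought, and lists rich in such genes share this limit. The TGF-beta response list went both ways (6 higher and 7 lower of 16, also adjusted over the list alone; median 0.34, with camera pointing down, adjusted p = 0.832). Ccn2 fell by 2.22. Epithelial markers held 5 higher and 2 lower of 13, also adjusted over the list alone (camera adjusted p = 0.495), with the keratin gene Krt8 up 2.15-fold. The NF-kB list held 8 higher and 7 lower of 24 (9 and 9 adjusted over the list alone; adjusted p = 0.421). The dissociation and heat shock list held 8 higher and 3 lower of 19, also adjusted over the list alone (adjusted p = 0.253). Muscle atrophy genes held 3 each way of 17 (the same adjusted over the list alone, adjusted p = 0.478) and macrophage and endothelial markers 1 higher and 2 lower of 6 (the same adjusted over the list alone; adjusted p = 0.615). In both the median was below 0 and the mean above. In all, edgeR called 5205 of 15794 genes between EO771 with C2C12 and EO771 alone, 2949 higher and 2256 lower (56.7% higher). With C2C12 counts subtracted at the share of muscle transcripts, 3396 were called, 1821 higher and 1575 lower. In a fit of all 28 libraries, 3386 were higher and 1536 lower (68.8% higher).

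**Figure D2:**
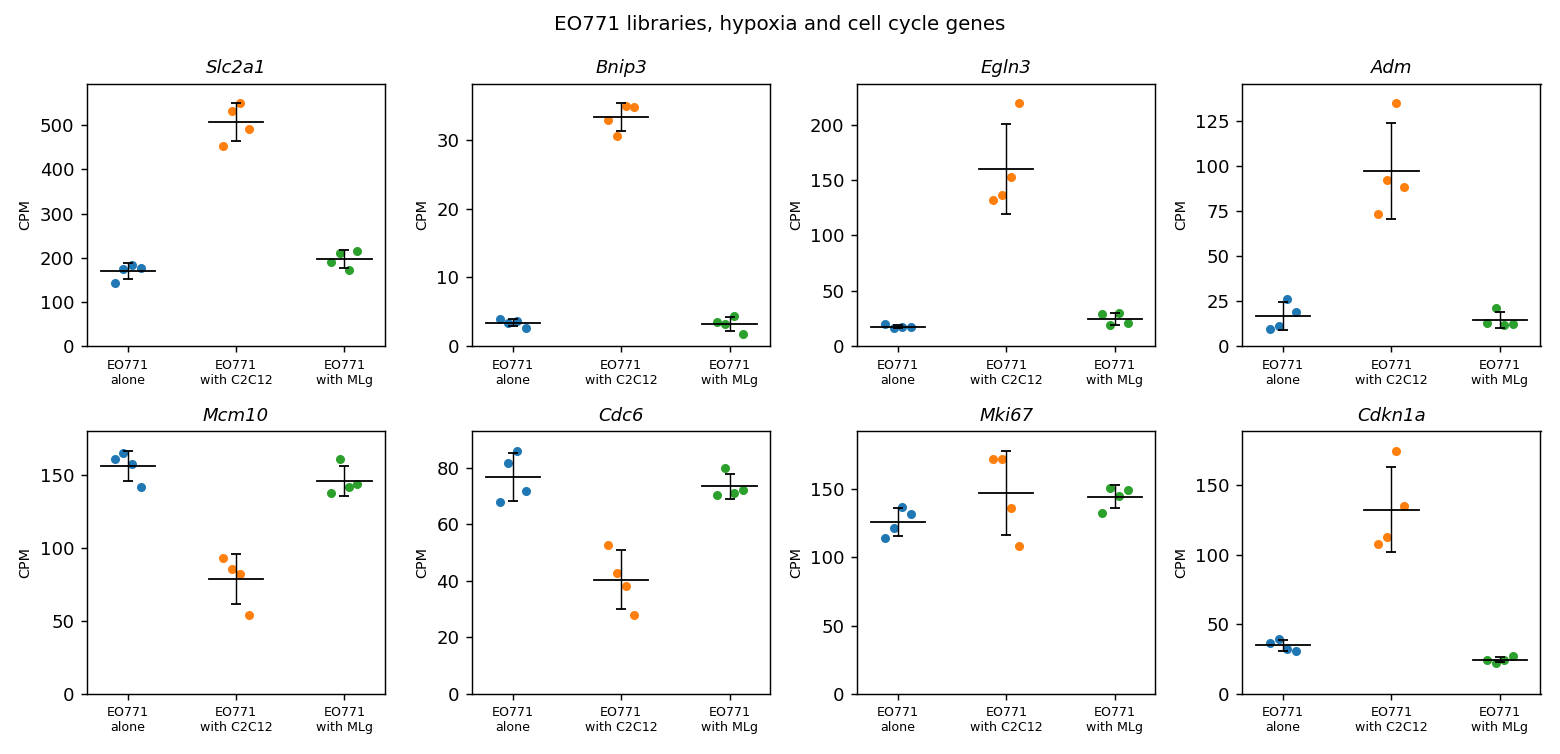
CPM (vertical axis) of 4 hypoxia genes and 4 cell cycle genes in the EO771 libraries; points are libraries, lines are group means and bars are SD (n = 4). Slc2a1, Bnip3, Egln3, Adm and Cdkn1a were higher, and Mcm10 and Cdc6 lower, in EO771 with C2C12 than in both other groups, while Mki67 was not called.

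In EO771 cells kept on MLg fibroblasts, the cornified envelope gene Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895) rose from 0.569 ± 0.248 to 21.8 ± 3.24 CPM (SD, n = 4, log2 5.27 ± 0.235 SE, adjusted p = 1.22e-10), the cytokine gene Il24 from 0.482 to 5.80 CPM and the integrin gene Itgb2 from 4.64 to 22.7 CPM. Lrrc15, a membrane protein gene (ENSMUSG00000052316, chromosome 16, 30269302 to 30283256), fell from 19.2 ± 3.35 to 1.36 ± 0.403 CPM (SD, n = 4, adjusted p = 1.52e-09), the collagen gene Col7a1 (ENSMUSG00000025650, chromosome 9, 108953586 to 108984875) from 118 to 8.53 CPM and Itga2 from 12.1 to 1.96 CPM. In the TGF-beta response list, Smad7, a feedback inhibitor of that pathway, fell by 2.33 on the log2 scale (adjusted p = 8.79e-09) and Ccn2 by 2.25. Of the 16 members, 5 were higher and 6 lower (7 each adjusted over the list alone; median 0.12, camera pointing down, adjusted p = 0.589). The 5 that were higher were all partner-enriched.

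Interferon response genes were higher in 21 of 27 cases and never lower (25 adjusted over the list alone; median 1.40, camera adjusted p = 2.01e-20, adjusted p = 0.14 with an estimated correlation). Of the 21, 15 were partner-enriched. Ifit1, an interferon-induced antiviral gene, rose from 3.58 ± 1.26 to 9.64 ± 1.89 CPM (SD, n = 4, adjusted p = 0.0002) and was at 4.12 CPM in MLg alone. In MLg with EO771, from which RNA could be carried over, Ifit1 was at 199 CPM. Ifit3 rose from 0.229 to 5.49 CPM. With partner counts subtracted the calls of Ifit1 (adjusted p = 0.0576) and Ifit3 (adjusted p = 0.0741) ended, while the list kept a median of 0.85 (camera, adjusted p = 7.11e-13). The hypoxia list had 2 of 29 members higher and 4 lower (3 and 4 adjusted over the list alone; median -0.08 and mean 0.30, camera adjusted p = 0.656). Bhlhe40, a circadian repressor gene, fell by 0.80 (adjusted p = 7.78e-05). Slc2a1 (170 against 197 CPM, adjusted p = 0.241), Bnip3 (3.42 against 3.21 CPM, adjusted p = 0.89) and Hif1a (346 against 307 CPM, adjusted p = 0.431) were not called. Of the 28 S phase genes edgeR called 0 (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.433). Of the 28 G2/M genes 1 was lower (0 adjusted over the list alone, camera adjusted p = 0.24). Without EO771 with MLg R6-1 the G2/M list passed the threshold at a median of -0.09 (camera, adjusted p = 0.0392). With the R number as a block, the G2/M and S phase lists both passed, at medians of -0.15 and -0.12 (camera, adjusted p = 0.000282 and 0.0481). Without EO771 with MLg R5-1 and R7-1, a choice made after the data were seen, the medians were 0.060 for G2/M, 0.038 for S phase and 0.082 for hypoxia, none of them called (camera, adjusted p = 0.639, 0.653 and 0.653). The glycolysis list then passed (median 0.16, adjusted p = 0.0284). Mki67 measured 126 ± 10.2 and 144 ± 8.38 CPM (SD, n = 4, adjusted p = 0.396). Myc fell by 0.64 on the log2 scale (adjusted p = 0.00303). Its call ended in a fit of all 28 libraries (adjusted p = 0.161) and with C2C12 counts subtracted at the share of muscle transcripts (0.056).

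Vegfa fell by 0.49 (adjusted p = 0.022) and Cdkn1a by 0.49 (adjusted p = 0.0217). Both missed the threshold without EO771 alone R3-1 (adjusted p = 0.057 and 0.0649), R3-2 (0.108 and 0.0888), or EO771 with MLg R5-1 (0.0671 and 0.0578) or R6-2 (0.0631 and 0.0569), and Vegfa also without R6-1 (0.0547). Cholesterol synthesis genes were higher in 5 of 23 cases and never lower (12 adjusted over the list alone; median 0.35, camera adjusted p = 3.13e-05, adjusted p = 0.549 with an estimated correlation). Extracellular matrix genes were higher in 13 of 25 cases and lower in 1 (15 and 1 adjusted over the list alone; median 0.63, adjusted p = 4.28e-11, adjusted p = 0.308 with an estimated correlation). Fibroblast markers were higher in 8 of 15 cases and lower in 1 (10 and 1 adjusted over the list alone; median 3.08, adjusted p = 1.63e-14, adjusted p = 0.0746 with an estimated correlation). All 13 and all 8 were partner-enriched, among them Fn1 (156 CPM beside 11100 CPM in MLg alone), and the medians were -0.14 and -0.09 after subtraction of partner counts, which put Fn1 at -8.58 here too. The chemokine gene Cxcl12, at 62.1 CPM, stood at 3683 CPM in MLg alone. Of the NF-kB list 7 of 24 were higher and 7 lower (7 and 10 adjusted over the list alone; adjusted p = 0.696). Ccl5 rose 3.00-fold. The dissociation and heat shock list had 5 of 19 higher and 1 lower (5 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.0407, adjusted p = 0.549 with an estimated correlation), led by the partner-enriched Egr1 (15.0 CPM beside 407 CPM in MLg alone). Its call ended without EO771 alone R3-2 (adjusted p = 0.0912) or R5-1 (0.0896), or EO771 with MLg R5-1 (0.0776) or R7-1 (0.207). In all, 1515 of 15794 genes were called, 946 higher and 569 lower (62.4% higher). A fit of all 28 libraries gave 1292 and 329 (79.7% higher). With partner-enriched genes left out, 706 were called (347 higher and 359 lower), and with partner counts subtracted 864 (389 and 475). With C2C12 counts in the same fit subtracted at the share of muscle transcripts instead, 396 were called.

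**Figure D3:**
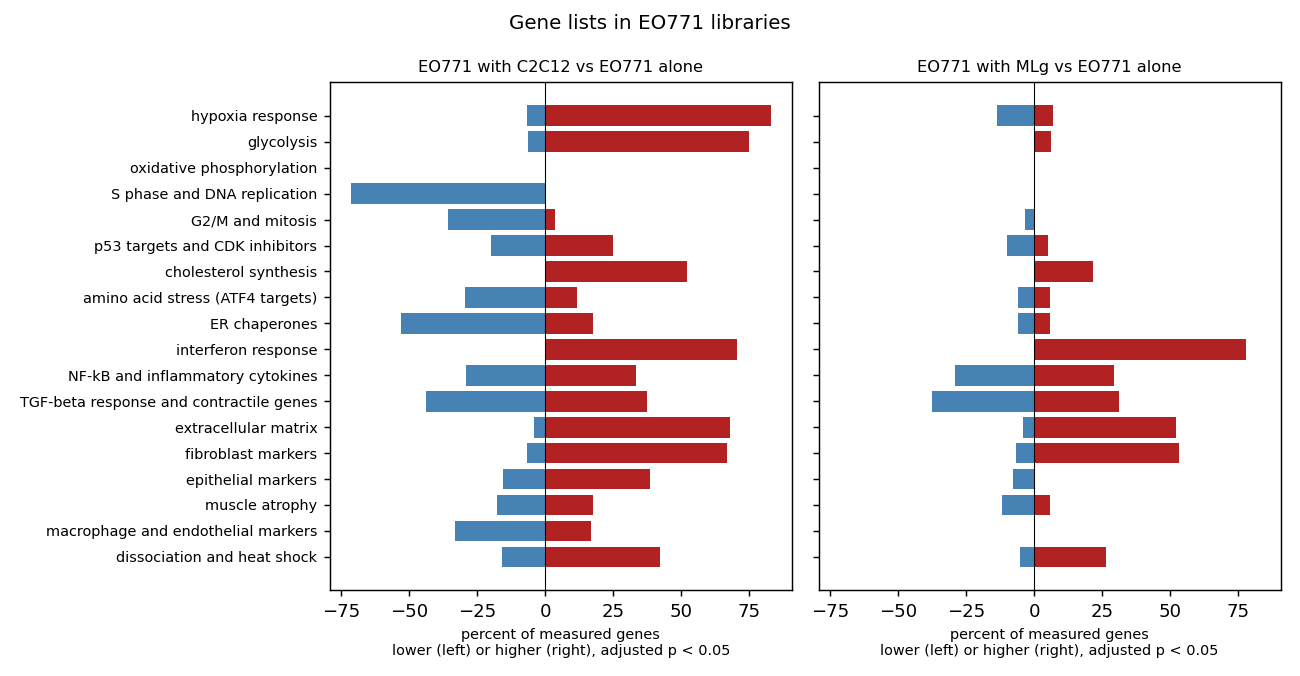
Percentage of the measured genes of each list (vertical axis) that were lower (left, blue) or higher (right, red) at an adjusted p under 0.05, for EO771 with C2C12 (left panel) and EO771 with MLg (right panel) against EO771 alone. The hypoxia list had 24 of 29 genes higher with C2C12 and 2 of 29 with MLg, and the S phase list 20 of 28 lower with C2C12 and 0 with MLg.

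A direct test between the co-cultured EO771 groups asked which differences belong to one partner. Hypoxia genes were higher with C2C12 than with MLg in 23 of 29 cases and lower in 2 (23 and 3 adjusted over the list alone; median 1.34, camera adjusted p = 1.42e-19, adjusted p = 0.00756 with an estimated correlation), 9 of the 23 partner-enriched. Bnip3 was 9.75-fold, Adm 6.28-fold, Egln3 6.17-fold, Pdk1 2.49-fold, Slc2a1 2.42-fold and Vegfa 2.04-fold higher. S phase genes were lower in 22 of 28 cases and never higher (23 adjusted over the list alone; median -0.39, adjusted p = 9.85e-09, adjusted p = 0.404 with an estimated correlation). At the share of muscle transcripts 6 were lower (median -0.29, adjusted p = 0.000226). Mcm10 fell by 0.98 and Cdc6 fell by 0.95 on the log2 scale. Cdkn1a was 5.08-fold (adjusted p = 2.22e-09) and Cdkn1b 1.40-fold higher (adjusted p = 0.00122), and Mki67 was not called (adjusted p = 0.772). Glycolysis genes were higher in 13 of 16 cases and never lower (14 and 1 adjusted over the list alone; median 0.63, adjusted p = 1.53e-09, adjusted p = 0.0853 with an estimated correlation). Loxl2, a lysyl oxidase gene (ENSMUSG00000034205, chromosome 14, 69609068 to 69695834), was at 79.4 ± 5.90 CPM with C2C12 and 8.15 ± 0.764 CPM with MLg (SD, n = 4, log2 3.20 ± 0.138 SE, adjusted p = 4.43e-11). The nitric oxide synthase gene Nos2 (chromosome 11, 78920787 to 78960254) was at 71.6 and 3.59 CPM. Atp7b was 39.9-fold and Krt8 1.97-fold higher with C2C12, and Igfbp5, at 38.5 against 0.0273 CPM, stood at 921 CPM in C2C12 alone. Calr, a calcium-binding chaperone gene, was lower by 0.83.

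Interferon genes were lower with C2C12 than with MLg in 10 of 27 cases and higher in 2 (13 and 3 adjusted over the list alone; median -0.51, adjusted p = 0.0197, adjusted p = 0.725 with an estimated correlation), with Ifit1 lower by 0.83. The list's call ended without EO771 with C2C12 R5-1 (adjusted p = 0.0691) or R5-2 (0.147) and after subtraction of partner counts (median -0.15, adjusted p = 0.567). For the G2/M list 8 of 28 genes were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.0177, adjusted p = 0.725 with an estimated correlation), with Foxm1 lower by 0.51. This call ended without EO771 with C2C12 R3-1 (adjusted p = 0.265) or EO771 with MLg R6-1 (0.077) or R6-2 (0.0557), with the R number as a block (0.0615), by fry (0.226) and in a fit of all 28 libraries (0.249). It also ended with C2C12 counts subtracted at the share of muscle transcripts (median -0.026, adjusted p = 0.634). In the fit of all 28 libraries the calls of Foxm1 (adjusted p = 0.0582) and Ifit1 (0.0536) ended. That of Ifit1 also ended after subtraction of partner counts (adjusted p = 0.0719). The largest falls were n-R5-8s1, a copy of the 5.8S ribosomal RNA gene (15.1 ± 12.9 CPM with MLg, 0.29 ± 0.579 CPM with C2C12; SD, n = 4), and Lars2, a mitochondrial leucyl-tRNA synthetase gene (1289 ± 803 and 343 ± 65.9 CPM; SD, n = 4). Both were highest in EO771 with MLg R5-1 and R7-1, at 25.8 and 26.5 CPM of n-R5-8s1 and 1411 and 2344 CPM of Lars2. Those libraries also had mitochondrial transcript shares of 11.7% and 10.0%, against 4.07% and 5.13% in the other two of the group. In all, 4371 of 15794 genes were called, 2368 higher and 2003 lower with C2C12, and 4060 were called without those libraries. With C2C12 counts subtracted at the share of muscle transcripts, 2759 were called.

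Because both responses were measured against the same 4 EO771 alone libraries, their fold changes are correlated by design. Over 15794 genes, which are not independent replicates, Pearson's r was 0.61 and the covariance 0.729. Simulated unchanged groups against the same controls gave 0.504 and 0.0589 (mean of 20 draws). Splitting the controls gave 0.545 and 0.744. Without partner-enriched genes r was 0.29 and the covariance 0.0766, and with the controls split as well 0.152 and 0.0476. Of the genes called in both responses, 713 were higher in both, where independent lists would share 177, and 244 were lower in both, where independent lists would share 81.3. With the controls split, so that each response had controls of its own, 369 and 79 were shared on average over 6 splits, where independent lists would share 82 and 23.1.

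In C2C12, contact with EO771 was marked by interferon response genes. Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) rose from 0.164 ± 0.0969 to 41.1 ± 15.5 CPM (SD, n = 4, log2 7.93 ± 0.456 SE, adjusted p = 3.27e-05), Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) from 1.80 ± 0.969 to 140 ± 33.4 CPM (SD, n = 4, adjusted p = 0.000157), Mx2 from 0.272 to 27.7 CPM, Oas2 from 0.047 to 9.78 CPM and Usp18, a deconjugating enzyme of ISG15, from 0.16 to 10.3 CPM. Of the 27 interferon genes, 26 were higher and 0 lower (27 adjusted over the list alone; median 4.11, camera adjusted p = 2.65e-65, adjusted p = 0.0179 with an estimated correlation). Of the 26, 6 were partner-enriched. EO771 alone held 0.301 CPM of Ifi44 and 3.58 CPM of Ifit1. Few genes fell: the collagen gene Col14a1 went from 36.5 ± 14.4 to 13.9 ± 1.43 CPM (SD, n = 4, adjusted p = 0.00867) and the metallothionein gene Mt2 fell by 1.14 on the log2 scale (adjusted p = 0.00686). Mt1 fell by 0.89 (adjusted p = 0.0214), but not past the threshold without C2C12 alone R2-1 (adjusted p = 0.0553) or C2C12 with EO771 R5-2 (0.0672) or R6-1 (0.0547). Mt1 and Mt2 were the 2 called members of the 19 muscle atrophy genes, also adjusted over the list alone (camera, adjusted p = 0.143). That list passed without C2C12 alone R3-2 (adjusted p = 0.0435).

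Cell cycle lists were higher in the co-cultured C2C12 libraries. In the G2/M list 1 of 28 genes was called (24 adjusted over the list alone; median 1.35, camera adjusted p = 4.26e-16, adjusted p = 0.388 with an estimated correlation). With the R number as a block the median was 0.51 (adjusted p = 2.78e-11). The 1 called gene was partner-enriched, and after subtraction of partner counts it was not called and the list's median was 0.70 (camera, adjusted p = 0.00693). In the S phase list 2 of 28 were called (9 adjusted over the list alone; median 0.35, adjusted p = 7.00e-08, adjusted p = 0.388 with an estimated correlation; with the block 0.20, adjusted p = 0.000143). Mcm10 rose from 1.39 to 6.87 CPM (adjusted p = 0.00194) beside 156 CPM in EO771 alone. After subtraction of partner counts neither Mcm10 (adjusted p = 0.362) nor the S phase list (median 0.10, adjusted p = 0.615) was called. Of the 9 epithelial markers 3 were higher (3 adjusted over the list alone; median 0.68, adjusted p = 3.26e-05, adjusted p = 0.388 with an estimated correlation), all partner-enriched, such as Krt8 at 5.52 CPM beside 93.3 CPM in EO771 alone. With the block this list was not called (median 0.077, adjusted p = 0.116). Pnma5 was at 12.7 ± 4.01 CPM, at 0 in all C2C12 alone libraries and at 277 CPM in EO771 alone. The NF-kB list had 3 of 20 higher and 0 lower (6 adjusted over the list alone; median 0.32, adjusted p = 0.000118, adjusted p = 0.0405 with an estimated correlation), the 3 being partner-enriched. Amino acid stress genes were higher in 2 of 18 cases (9 higher and 1 lower adjusted over the list alone; median 0.53, adjusted p = 8.57e-05, adjusted p = 0.497 with an estimated correlation), both partner-enriched, and had a median of 0.25 with the block (adjusted p = 0.0112) and of -0.11 after subtraction of partner counts. Of the 31 hypoxia genes edgeR called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2), with a median of 0.07 (camera, adjusted p = 0.393). Slc2a1 measured 117 ± 49.5 and 162 ± 27.8 CPM (SD, n = 4, adjusted p = 0.65) and Mki67 22.2 ± 9.92 and 41.4 ± 18.4 CPM (SD, n = 4, adjusted p = 0.571). The hypoxia list passed the threshold without C2C12 alone R2-1 (median 0.20, adjusted p = 0.0477) or R5-1 (0.24, adjusted p = 0.0454).

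Muscle transcripts varied between C2C12 libraries of 1 group: the mean log2 CPM of the sarcomere list was 6.79, 3.11, 4.10 and 7.22 in C2C12 alone R2-1, R3-1, R3-2 and R5-1, and 4.30, 6.42, 6.30 and 6.03 in C2C12 with EO771 R3-1, R5-1, R5-2 and R6-1. Of its 24 genes edgeR called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2), and the median was -0.26 with camera pointing up (adjusted p = 0.342). The list passed with a median of 0.05 without C2C12 alone R2-1 (adjusted p = 0.00224), of 0.36 without R5-1 (adjusted p = 0.00231), and of -0.01 without C2C12 with EO771 R3-1 (adjusted p = 0.021). Without the 3 libraries numbered R3, a choice made after the data were seen, its median was -0.87 (adjusted p = 7.35e-20). These adjusted p values rest on the preset correlation of 0.01, while the correlation estimated for this list was 0.978. In the fit of all C2C12 libraries the list was not called with that estimate (camera, adjusted p = 0.922) or by fry (0.90). It passed with medians of either sign, so these passes are not taken as a change of muscle transcripts. The small shifts of the cholesterol, ER chaperone, TGF-beta and dissociation lists (medians 0.23, 0.21, -0.24 and -0.29; adjusted p = 0.00387, 0.013, 0.0249 and 0.0202) held 0 genes called by edgeR each (2, 3, 3 and 5 at an unadjusted p under 0.05, and 0, 0, 0 and 2 by DESeq2). They were not called with the R number as a block (adjusted p = 0.302, 0.325, 0.615 and 0.178), nor with an estimated correlation (0.617, 0.497, 0.595 and 0.388). Their calls also ended without single libraries. For cholesterol these were C2C12 alone R2-1 (adjusted p = 0.0648) and C2C12 with EO771 R5-2 (0.0675), and for ER chaperones C2C12 alone R2-1 (0.075) and C2C12 with EO771 R5-1 (0.0583) and R6-1 (0.0758). For TGF-beta they were C2C12 alone R3-1 (0.187) and R3-2 (0.161) and C2C12 with EO771 R5-2 (0.181) and R6-1 (0.133), and for dissociation C2C12 alone R3-2 (0.0562) and C2C12 with EO771 R5-2 (0.0675) and R6-1 (0.105). In all, edgeR called 445 of 16625 genes, 429 higher and 16 lower (384 with the block, 816 by DESeq2), and 306 without C2C12 with EO771 R6-1. With partner-enriched genes left out 84 were called, and 124 with partner counts subtracted.

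In MLg, interferon genes were also the leading rise with EO771. Ifit1 rose from 4.12 ± 0.467 to 199 ± 52.0 CPM (SD, n = 4, log2 5.62 ± 0.219 SE, adjusted p = 3.09e-08), Ifi44 from 1.46 to 69.0 CPM, Isg15 from 4.07 to 109 CPM, Mx2 from 2.27 to 43.6 CPM and Rsad2, which encodes viperin, from 0.114 to 10.7 CPM. All 27 measured interferon genes were higher (27 adjusted over the list alone; median 3.19, camera adjusted p = 2.17e-40, adjusted p = 0.202 with an estimated correlation). Of these 4 were partner-enriched. The inflammatory list had 9 of 20 higher and 0 lower (10 adjusted over the list alone; median 0.52, adjusted p = 2.51e-06, adjusted p = 0.292 with an estimated correlation). The chemokine gene Ccl5 rose from 0.765 to 10.5 CPM and Saa3 from 2.81 to 9.75 CPM. The matrix metalloproteinase genes Mmp13 and Mmp3 rose 3.32-fold and 2.22-fold, Itga2 fell from 35.1 to 11.2 CPM and Lrrc17 from 17.3 to 7.00 CPM. Cholesterol synthesis genes were lower in 16 of 23 cases and higher in 1 (17 and 1 adjusted over the list alone; median -0.63, adjusted p = 3.56e-07, adjusted p = 0.435 with an estimated correlation). The sterol reductase gene Tm7sf2 fell by 1.17 on the log2 scale (adjusted p = 0.00389). The contractile genes Myl9 and Acta2 fell by 0.54 and 0.46 (adjusted p = 0.00284 and 0.0145). Their list was not called (2 higher and 3 lower of 18, also adjusted over the list alone; adjusted p = 0.172), and neither gene was called after subtraction of partner counts (adjusted p = 0.0657 and 0.159).

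**Figure D4:**
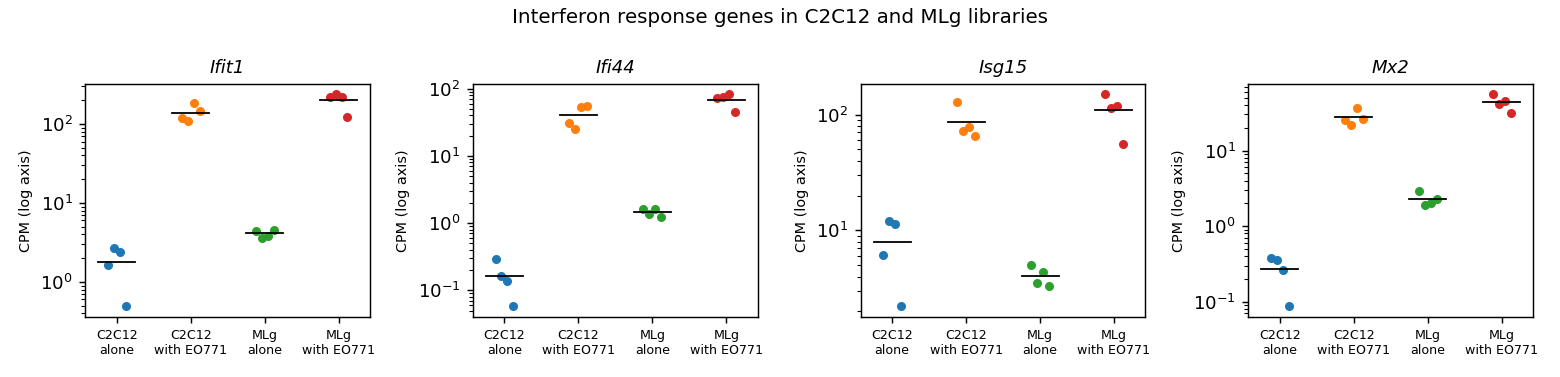
CPM (vertical log axis) of 4 interferon response genes in C2C12 and MLg libraries alone and with EO771; points are libraries and lines are group means (n = 4). In each gene and each line all 4 co-cultured libraries lay above all 4 libraries alone, with Ifit1 rising from 1.80 to 140 CPM in C2C12 and from 4.12 to 199 CPM in MLg.

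The G2/M list was higher in 25 of 28 genes in MLg with EO771 (25 adjusted over the list alone; median 0.50, camera adjusted p = 2.64e-16, adjusted p = 0.221 with an estimated correlation), 16 of them partner-enriched. After subtraction of partner counts the median was 0.24 (adjusted p = 1.51e-07). Ube2c rose 2.02-fold and the kinase gene Aurka 1.89-fold, at 26.5 CPM beside 117 CPM in EO771 alone, and Aurka was not called after the subtraction (adjusted p = 0.0996). The S phase list was higher in 11 of 28 genes and never lower (15 adjusted over the list alone; median 0.37, adjusted p = 5.79e-08, adjusted p = 0.435 with an estimated correlation), 9 of the 11 partner-enriched, among them Rrm2 (2.09-fold, beside 328 CPM in EO771 alone; adjusted p = 0.874 after subtraction). Glycolysis genes were higher in 10 of 16 cases and never lower (10 adjusted over the list alone; median 0.31, adjusted p = 1.69e-05, adjusted p = 0.435 with an estimated correlation), 7 of them partner-enriched. The lactate exporter gene Slc16a3, at 32.2 CPM beside 355 CPM in EO771 alone, had a log2 value of -0.09 after subtraction, and the list was then not called (adjusted p = 0.883). Galnt3 was at 11.5 ± 3.23 CPM, at 0 in MLg alone and at 101 CPM in EO771 alone. Mki67 measured 135 ± 10.3 and 141 ± 21.6 CPM (SD, n = 4, adjusted p = 0.644). Of 30 hypoxia genes 5 were higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.418), 4 of the 5 partner-enriched. Pdk1 fell by 0.41 and Ndrg1 by 0.50 (adjusted p = 0.0124 and 0.0149), and Hif1a was at 173 and 150 CPM (adjusted p = 0.0902). With partner counts subtracted, Hif1a was called lower (log2 -0.31, adjusted p = 0.0221) and Ndrg1 was not called (adjusted p = 0.0581). In the fit of all 28 libraries neither Pdk1 (adjusted p = 0.113) nor Ndrg1 (0.235) was called. The dissociation and heat shock list was higher in 8 of 20 genes (9 adjusted over the list alone; median 0.57, adjusted p = 6.02e-05, adjusted p = 0.435 with an estimated correlation). Muscle atrophy genes (2 of 19 higher and 1 lower, 3 and 1 adjusted over the list alone; median 0.16, adjusted p = 0.0406, adjusted p = 0.435 with an estimated correlation) lost the call without MLg alone R3-2 (adjusted p = 0.0798) or R5-2 (0.0767), or MLg with EO771 R6-1 (0.0849) or R6-2 (0.0971). In all, 2472 of 16823 genes were called, 1663 higher and 809 lower (67.3% higher). A fit of all 28 libraries gave 1414 and 276 (83.7% higher). Without MLg alone R6-1 or R6-2 the number was 1627 or 1569, with partner-enriched genes left out 1311, and with partner counts subtracted 783.

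The host responses to EO771 were compared directly. The interferon gene Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907) rose from 0.0109 to 4.62 ± 2.12 CPM in C2C12 and from 13.3 to 49.8 ± 14.3 CPM in MLg (SD, n = 4, adjusted p of the difference = 0.000133). By summed counts the ratio was 468 in C2C12, with a counting interval of 160 to 2270 because C2C12 alone held 3 counts in all, and 3.54 in MLg (3.40 to 3.68). These intervals leave out the spread between libraries. Hes1, a Notch target gene (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), rose by 2.35 in MLg and measured -0.32 in C2C12, a difference of -2.65 ± 0.325 (SE, adjusted p = 0.000125). Gbp7 differed by 2.45, Npy1r by 3.28 and Mt1 by -0.95. These 3 calls ended with partner counts subtracted (adjusted p = 0.059, 0.059 and 0.102), and that of Gbp7 also with the R number as a block (0.0577). The interferon list differed by a median of 0.97 toward C2C12 (8 of 27 higher and 0 lower, 16 and 3 adjusted over the list alone; camera adjusted p = 3.3e-10, adjusted p = 0.35 with an estimated correlation). Some members were near the floor in C2C12 alone, as Mx1 was, where log2 differences are unsure. The list's mean log2 CPM per library, with a small offset, was 1.183 to 1.583 in C2C12 alone and 4.295 to 4.838 with EO771. In MLg it was 2.91 to 3.154 alone and 5.236 to 5.963 with EO771, the higher level. Cholesterol synthesis differed by 0.88 (1 each way of 23, 13 and 1 adjusted over the list alone; adjusted p = 8.67e-09, adjusted p = 0.542 with an estimated correlation) and G2/M by 0.75 (0 of 28 by edgeR, also adjusted over the list alone, 9 at an unadjusted p under 0.05, 0 by DESeq2, adjusted p = 6.54e-07, adjusted p = 0.618 with an estimated correlation). In C2C12 itself the G2/M median was 0.51 with the R number as a block, beside 0.50 in MLg without one. Neither value had partner counts subtracted, which lowered the G2/M median in both lines. Block and subtraction were not combined, so these medians do not show equal responses of the host cells. The lowest C2C12 library in this list was C2C12 alone R2-1 (mean log2 CPM 1.72) and the highest C2C12 with EO771 R6-1 (4.275). Neither has a library of equal R number in the other C2C12 group. The dissociation and heat shock list differed by -1.07 (0 higher and 1 lower of 20, 0 and 10 adjusted over the list alone; adjusted p = 1.95e-07, adjusted p = 0.239 with an estimated correlation). In all, 343 of 18647 genes differed, 145 toward C2C12 and 198 toward MLg (726 by DESeq2), but 18 with partner-enriched genes left out and 37 with partner counts subtracted, and 474 without C2C12 with EO771 R3-1.

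Grown alone, C2C12 and MLg differed in most genes tested. The muscle genes Myh1 (236 ± 256 CPM in C2C12, 0.00405 ± 0.0081 CPM in MLg), Chrna1 (261 and 0.0625 CPM) and Myf5 (24.2 and 0.00718 CPM) were higher in C2C12, as were all 24 sarcomere genes (24 adjusted over the list alone; camera adjusted p = 1.06e-09, adjusted p = 0.366 with an estimated correlation). The matricellular gene Postn was at 853 CPM in C2C12 and 14.2 CPM in MLg, and Hoxb9 at 0 and 118 CPM. C2C12 had 26 of 31 hypoxia genes higher and 3 lower (the same adjusted over the list alone; median 1.51, adjusted p = 1.49e-06, adjusted p = 0.366 with an estimated correlation), including Car9 at 188 ± 28.0 CPM against 2.20 ± 0.426 CPM (SD, n = 4) and Egln3 at 72.7 against 2.56 CPM. All 16 glycolysis genes were higher (16 adjusted over the list alone; median 1.91, adjusted p = 5.98e-09, adjusted p = 0.366 with an estimated correlation), with Slc16a3 at 66.0 against 1.48 CPM. All 28 G2/M genes were lower (28 adjusted over the list alone; median -2.40, adjusted p = 1.06e-09, adjusted p = 0.366 with an estimated correlation), with Top2a at 25.7 against 224 CPM. Of 28 S phase genes 26 were lower (26 adjusted over the list alone; median -1.25, adjusted p = 6.14e-09, adjusted p = 0.366 with an estimated correlation), with Mcm5 at 7.14 against 61.1 CPM. Interferon genes were lower in C2C12 in 23 of 27 cases and higher in 2 (the same adjusted over the list alone; median -2.12, adjusted p = 1.57e-07, adjusted p = 0.366 with an estimated correlation), with Mx1 at 0.0109 against 13.3 CPM. Ccl2 was at 24.1 against 497 CPM and Fdps at 5.82 against 29.4 CPM. In all, 11250 of 18647 genes were called, 5716 higher and 5534 lower in C2C12.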

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

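The tests of the R number, of carry-over into the interferon genes of the host lines and of the share of muscle transcripts, the subtraction at that share, the pairs parted by the splits and the counting interval of Mx1, were chosen after the results were seen. The single libraries below were picked because they lay far from the other 3 of their group, which happened in 18 of 262 groups of values, while chance gives about 1 in 20; over all genes that the rule names it was 59 of 614.

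In C2C12 alone, R5-1 held 10.6 CPM of the replication gene Mcm5 (5.71 to 6.23 in the others), 9.61 CPM of the sterol synthesis gene Fdps (4.41 to 4.67) and 0.0435 CPM of Mx1 (0 in the others). In MLg alone, R3-2 held 22.5 CPM of Itga2 (37.8 to 40.3), 104 CPM of Npy1r (145 to 152), 0.918 CPM of Egln3 (2.89 to 3.24), 17.3 CPM of Postn (13.0 to 13.4), 52.0 CPM of Fdps (21.1 to 22.5) and 0.0287 CPM of Myf5 (0 in the others). In the same group R5-2 held 3.76 CPM of Hes1 (2.01 to 2.14) and R6-2 held 0.0162 CPM of Myh1 (0 in the others). In EO771 alone, R5-1 held 0.0571 CPM of Igfbp5 (0 in the others). In C2C12 with EO771, R3-1 held 3.68 CPM of Mcm10 (7.71 to 8.18). In EO771 with C2C12, R5-2 held 1.16 CPM of n-R5-8s1 (0 in the others). In MLg with EO771, R6-2 held 100 CPM of Ndrg1 (132 to 137) and R5-1 held 20.1 CPM of Hes1 (9.44 to 10.9). In EO771 with MLg, R5-1 held 7.80 CPM of Ifit3 (4.63 to 4.86) and 20.9 CPM of Adm (11.8 to 13.0). The values of Mx1, Myf5, Myh1 and Igfbp5 are at most 3 counts, which a count of 0 also allows, so these 4 do not stand apart from the zeros.

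The response to EO771 differed between C2C12 and MLg, by a test of the difference itself, for 5 named genes: Gbp7 by 2.45 on the log2 scale, Mx1 by 6.58, Hes1 by -2.65, Mt1 by -0.95 and Npy1r by 3.28. It also differed for 7 lists, with median differences of 0.97 for interferon response, 0.88 for cholesterol synthesis, 0.75 for G2/M, -0.23 for glycolysis, -0.12 for oxidative phosphorylation, -0.26 for muscle atrophy and -1.07 for dissociation and heat shock. None of these 7 lists passed with an estimated correlation (adjusted p = 0.35, 0.542, 0.618, 0.618, 0.899, 0.17 and 0.239). By fry the adjusted p values were 0.0465, 0.26, 0.37, 0.307, 0.683, 0.0238 and 0.0465. The interferon difference includes members near the floor in C2C12 alone. The G2/M difference includes C2C12 libraries with no match in R number. The glycolysis list held 1 of 16 genes called lower, and the muscle atrophy list 2 of 19. Of the 28 oxidative phosphorylation genes edgeR called 0 (1 at an unadjusted p under 0.05, 1 by DESeq2). The call of glycolysis ended without C2C12 alone R5-1 (adjusted p = 0.0558) or C2C12 with EO771 R3-1 (0.0566). That of oxidative phosphorylation ended without C2C12 alone R5-1 (0.0558), C2C12 with EO771 R5-2 (0.208) or R6-1 (0.20), MLg alone R3-2 (0.0534), or MLg with EO771 R5-1 (0.068) or R6-1 (0.0621). Mx1 started at 0.0109 CPM in C2C12 alone, 3 counts in all, and 13.3 CPM in MLg alone. Its 6.58 therefore depends on the prior count of the fit; the ratio in C2C12 was 468, with a counting interval of 160 to 2270, against 3.54 in MLg.

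The hypoxia list was higher in EO771 with C2C12 than in EO771 alone (median 1.48). Carry-over of C2C12 RNA was tested by subtracting partner counts, which left a median of 1.22, and subtraction at the larger share of muscle transcripts also left 1.22. A difference between R numbers was tested with a block, which left 1.48, so the tables argue against either as the whole cause. Low oxygen or another signal in the shared culture stays open and was not tested, since no library measured oxygen.

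The interferon list was higher in both host lines with EO771. For each member that rose, the mean carry-over share was multiplied by the EO771 level in co-culture minus the host's level alone. The median of this over the rise was 0.123% in C2C12 and -0.21% in MLg, which argues against carried EO771 RNA as the source. A value below 0 means that the EO771 level was below that of the host alone. In EO771 with MLg the list kept a median of 0.855 after subtraction of MLg counts, which argues against MLg RNA at the median share as the whole cause. No larger share was tried for MLg, so carry-over at a larger share and a response of the EO771 cells cannot be told apart. In EO771 with C2C12 the list kept 0.995 after the planned subtraction but 0.03 at the share of muscle transcripts. There too carry-over and a response of the EO771 cells cannot be told apart, because the share that applies to interferon genes is unknown. A response to contact in the host lines stays open and was not tested further.

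Muscle transcripts in EO771 with C2C12 stood above the share of other C2C12 transcripts: 18 muscle genes were at 5.48%, 7.98%, 19.9% and 3.76% of the C2C12 level in R5-1, R5-2, R6-1 and R3-1, and 395 other genes at 0.571%, 0.789%, 1.33% and 1.22%. The C2C12 level is the mean of the co-cultured C2C12 libraries. Their sarcomere list had a mean log2 CPM of 4.30 in R3-1 and 6.03 to 6.42 in the others, so the ratio of each library is approximate. The lowest ratio was 3.08, which argues against carry-over of all C2C12 transcripts at 1 share. Carry-over of a muscle-rich fraction, such as pieces of myotubes, may be the source of the ratio of 3.08 or more, and was not tested.

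For each comparison, the number of genes called was set against other splits of the same libraries. The real split was the only 1 of 35 to call as many genes in EO771 with C2C12 against alone (5205, highest other 2), EO771 with MLg against alone (1515, highest other 1), the co-cultured EO771 groups (4371, highest other 0), MLg (2472, highest other 0) and the host lines alone (11250, highest other 0). That is the smallest share that 35 splits can give, so the count by itself does not exclude chance. In the comparisons of co-cultured groups, carried partner RNA also marks the real groups, which favours the real split in advance. In C2C12, 2 of 35 splits called as many (445, highest other 920), so chance cannot be excluded by this count. The split with 920 sets C2C12 alone R2-1, R3-1 and R3-2 with C2C12 with EO771 R3-1 against the rest and parts 0 of 6 pairs of equal R number, which points to a structure of the samples. Among the 27 splits that part 4 pairs, as the real one does, only the real one calls as many (highest other 0), and with the R number as a block 384 genes were called. For the difference of host responses, the real split was the only 1 of 60 to call as many (343, highest other 289). The split with 289 parts 4 pairs of C2C12 libraries, as the real one does, and the next, with 251, sets the C2C12 libraries apart as the split with 920 does. The structure of the C2C12 libraries thus enters this count, so chance is not taken as excluded by it. With the R number as a block 361 genes were called.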

How the results depend on the processing

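The alternatives with even counts halved, without the C2C12 libraries numbered R3, without EO771 with MLg R5-1 and R7-1, and with C2C12 counts subtracted at the share of muscle transcripts were chosen after the data were seen. For the named genes, direction and side of the threshold were kept in 641 of 652 values in EO771 with C2C12 against alone, 365 of 390 in EO771 with MLg against alone, 369 of 372 between the co-cultured EO771 groups, 209 of 215 in C2C12, 349 of 361 in MLg, 117 of 124 for the difference of host responses and 195 of 195 between the host lines alone. For the lists they were kept in 323 of 337, 311 of 339, 304 of 337, 279 of 318, 285 of 300, 449 of 478 and 261 of 280 values. These list counts leave out the tests with an estimated correlation and with fry, under which many list calls ended. In EO771 with C2C12 against alone, only the hypoxia list passed with an estimated correlation (camera, adjusted p = 0.0145). Over every gene that the rule names, direction and side of the threshold were kept in 1099 of 1125, 774 of 878, 1051 of 1090, 499 of 581, 883 of 976, 328 of 466 and 718 of 735.

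With partner counts subtracted, the number of genes called was 864 in EO771 with MLg against alone, 124 in C2C12, 783 in MLg and 37 for the difference of host responses. Medians turned to -0.77 for TGF-beta and -0.38 for fibroblast markers in EO771 with C2C12, to -0.28, -0.14 and -0.089 for TGF-beta, matrix and fibroblast markers in EO771 with MLg, and to -0.11 and -0.17 for amino acid stress in C2C12 and MLg. Slc16a3 in MLg was at -0.088, and Fn1 at -8.58 in both EO771 comparisons with EO771 alone. With partner-enriched genes left out, which tests fewer genes, the numbers were 706, 84, 1311 and 18 in the same order, and medians were -0.70 and -0.88 for TGF-beta with C2C12 and MLg, -0.13 for matrix with MLg and -0.055 for amino acid stress in C2C12.

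With C2C12 counts subtracted at the share of muscle transcripts, 3396, 396 and 2759 genes were called in the EO771 comparisons (with C2C12 against alone, with MLg against alone, and with C2C12 against with MLg). In the first, medians were -0.095 for G2/M, -1.57 for TGF-beta, -1.37 for matrix, -3.02 for fibroblast markers and -0.29 for myogenic regulators, with Car9 at -4.37 and Fn1 at -8.54. In the second they were -0.27, -0.13 and -0.075 for TGF-beta, matrix and fibroblast markers, with Fn1 at -8.54. In the third they were -0.026 for G2/M, -1.47 for matrix and -0.17 for myogenic regulators. MLg counts were subtracted at their median share at the same time, so 396 compares with 864 above. The G2/M calls ended (adjusted p = 0.338 and 0.634). Both subtractions put Fn1 below the control, so both remove more of such genes than carry-over brought.

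By DESeq2, 816 genes were called in C2C12 and 726 for the difference of host responses, and in 1 fit of all 28 libraries 1176 and 549; the cause was not tested. In that fit the G2/M list between the co-cultured EO771 groups had a median of -0.13 (adjusted p = 0.249). With an estimated correlation the S phase and G2/M lists had adjusted p = 0.305 and 0.595 in EO771 with C2C12 (medians -0.45 and -0.25) and 0.404 and 0.725 between the co-cultured EO771 groups (-0.39 and -0.13), and by fry the G2/M list had 0.0811 (-0.25) and 0.226 (-0.13). With the R number as a block, medians were 0.70 for sarcomere in the difference of host responses, -0.068 for cholesterol and -0.22 for myogenic regulators in C2C12 (adjusted p = 0.302 and 0.0126), -0.15 for G2/M between the co-cultured EO771 groups (adjusted p = 0.0615), and -0.15 and -0.12 for G2/M and S phase in EO771 with MLg (adjusted p = 0.000282 and 0.0481); the cause was not tested. Without the C2C12 libraries numbered R3, the hypoxia median was -0.10 in C2C12 (adjusted p = 0.0349) and -0.24 in the difference of host responses. Without EO771 with MLg R5-1 and R7-1, the cholesterol median between the co-cultured EO771 groups was -0.13. The carry-over share from summed counts in EO771 with C2C12 was 1.47%.

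Leaving out each library in turn gave 4139 to 4860 genes in EO771 with C2C12 against alone, 1146 to 1530 in EO771 with MLg against alone, 3061 to 4252 between the co-cultured EO771 groups, 306 to 596 in C2C12, 1569 to 2994 in MLg (1627 without MLg alone R6-1 and 1569 without R6-2), 248 to 474 for the difference of host responses and 10587 to 10846 between the host lines alone. Medians ranged from -0.21 to -0.024 for G2/M between the co-cultured EO771 groups, -0.086 to -0.018 for G2/M in EO771 with MLg, -0.66 to 0.36 for sarcomere and -0.13 to 0.056 for oxidative phosphorylation in C2C12, and -0.44 to 0.52 for sarcomere in the difference of host responses. Depth limits genes near the floor. The halved even counts and the subtractions lowered counts, and no alternative tested depth by itself.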

Other observations

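The counts of shared genes without partner-enriched ones were chosen after the results were seen. Hif1a transcripts were not called in EO771 with C2C12 against alone or against EO771 with MLg (adjusted p = 0.934 and 0.228), while targets of its protein were. Hif1a measured 346 ± 11.9 CPM in EO771 alone, 368 ± 35.9 CPM with C2C12 and 307 ± 41.0 CPM with MLg (SD, n = 4). Without partner-enriched genes, 242 genes were higher and 217 lower in both EO771 responses. With the controls split, so that each response had controls of its own, 86.2 and 72.3 were shared on average, where independent lists would share 12.1 and 22.2.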
